A study of Rattus norvegicus with 16 samples.

How the data were processed

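Gene expression was measured in 2 respiratory muscles of male Sprague-Dawley rats, the diaphragm and the intercostal muscle of the chest wall, on 16 one-colour arrays. Per the labels' protocols, rats of the occlusion group underwent trials of tracheal occlusion lasting 5 to 8 s with about 25 s of recovery, in daily sessions for 10 days, and surgical controls attended the sessions without occlusions. The groups were taken from the sample titles, with 4 arrays in each of 4 groups. Each muscle was hybridised on 1 slide of its own, per the labels, so muscle and slide cannot be told apart. Animal codes in the labels match between the muscles for 6 of the 8 positions, so the arrays of each muscle come from separate animals while most animals contributed an array to both muscles.

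The authors' deposited values are fluorescence intensities on a linear scale, 1 per feature for 62976 features. Per the labels' protocols, total RNA was labelled with Cy3. Agilent Feature Extraction is named in the submitters' processing notes without a version; the background correction, any scaling and the genome build are not given in the sources used here. Median intensity per array ran from 280 to 1020, a ratio of 3.64, and the log2 75th percentiles spanned 2.11, so the arrays had not been brought to a common level. On 14 of the arrays between 1973 and 5625 features shared the array's lowest value, as a floor does; on the arrays labelled occlusion intercostal 3 and control diaphragm 1 only 2 and 4 features did. The highest intensities of these arrays were 3050000 and 1040000, against 736000 to 778000 on the others. Whether these arrays were scanned and extracted with the same settings is not given in the sources used here.

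Features carry only a running number in the table used here, and the reference table of gene names could not be joined to it. Every feature was therefore tested singly, no gene is named, and at most 2 feature numbers per direction are printed for each comparison. Control features and repeated features of 1 probe could not be set aside or averaged, so counts are of features, not genes. The 44 gene lists and the named genes fixed before the data were examined could not be tested, and neither could the averaging of probes per gene.

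Intensities were put on the log2 scale and each array was shifted to a common 75th percentile, as fixed for the case that these percentiles differed by over 0.2. The 40% of features with the lowest mean over all arrays were left out, which left 37786. Occlusion and control arrays were compared within each muscle with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference of the occlusion effects between the muscles, and the difference between the muscles of control rats, were contrasts in a limma fit of all 16 arrays in 4 groups with 1 shared estimate of the spread. Features named in the text were chosen by a rule fixed before the data were examined: for each direction, those past the threshold with no overlap between the groups, by size; where too few passed, those with a fold of at least 1.5 and no overlap, by unadjusted p, given as not past the threshold. The first 2 per direction are printed.

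Replicate numbers do not pair occlusion with control arrays of 1 muscle, which come from different animals. Between the muscles the pairing comes from the animal codes, and was used as a random block (duplicateCorrelation, statmod 1.5.0) in an alternative. The deviations of the diaphragm and intercostal arrays of the same animal code correlated at between -0.42 and 0.35 across features.

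The alternatives fixed before the data were examined were quantile normalization, a common median, no filter, a filter of 60%, eBayes with trend and robust set, array weights, the replicate number, animal code, first digit of the animal code or row of the array on the slide as a block, all arrays in 1 fit, a plain test with equal variances, and each array left out in turn. Others were chosen after seeing the data. The order of the features on the array was inferred from the values: deviations from the median over the arrays were most alike at a distance of 164 features, which gives 384 rows and 164 columns. A smooth trend over the array surface was then removed in 2 ways. The first used 1 trend for all features (Gaussian smoothing with an SD of 4 features, deviations limited to 2 on the log2 scale). Because this version moved the muscle difference of the array's zones in opposite directions, a version with separate trends in 6 classes of brightness (SD of 6 features) was made after its result was seen, and both are reported. Further added alternatives used only the rows from 281 on, or left out 4 arrays that stood apart. In the alternative with row as a block, the coding run first compared the muscles at row 1, where each control group has 1 array; the comparison at the mean of the 2 rows was added after its result was seen, and both are given.

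Each test was tried on simulated arrays drawn from the real means and residual spreads, with 200 of 37786 features changed. For the intercostal comparison 0% of features changed 1.5-fold, 14% of those changed 2-fold, 62% of those changed 4-fold and 90% of those changed 8-fold were recovered. For the diaphragm comparison the shares were 0%, 18%, 70% and 88%. For the difference of the effects they were 0%, 8%, 48% and 80%, and for the control muscles 2%, 30%, 74% and 94%. These simulated arrays carried no spatial pattern. Far more features, 7696, differed between the real control muscles than the 200 simulated. The shares for that test may therefore not carry over. On simulated arrays that carried the estimated spatial trends and no muscle difference, 1308 features passed the muscle contrast before the trend was removed within brightness classes and 0 after. The same smoothing estimated and removed these trends, so this cannot show that patterns of another shape or scale would be removed.

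To place each array between the muscles, features of high signal (both control means above the 60th percentile) that differed at least 2-fold between the control muscles without overlap were taken, with the array itself left out of the reference. Its position was set to 0 at the control intercostal mean and 1 at the control diaphragm mean. No array was moved to another group.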

Results

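Expression was profiled in the diaphragm and in the 3rd parasternal intercostal muscle of rats after 10 daily sessions of brief tracheal occlusions, a stimulus that loads the inspiratory muscles, and in surgical controls. The series title asks which expression changes go with enlargement of these muscles. There were 4 arrays in each of 4 groups, and features carry numbers that the files used here do not pair with gene names. Median intensity per array ran from 280 on the array labelled occlusion intercostal 3 to 1020 on the array labelled occlusion diaphragm 1. Across the 37786 features tested, array pairs of the same group had a median Pearson correlation of 0.955 (24 pairs), pairs of 1 muscle from different treatments 0.953 (32 pairs) and pairs from different muscles 0.902 (64 pairs). These correlations run across features, which are not independent replicates. The first principal component held 38.0% of the variance and the second 15.6%. No pair of arrays held identical values, and the most alike pair correlated at 0.984.

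On features that set the control muscles apart, 2 arrays did not lie clearly with the muscle of their label. On features higher in control diaphragm, in the rows of the array from 281 on, the array labelled occlusion intercostal 1 had a median position of 1.06 over 133 features, where 0 is the control intercostal and 1 the control diaphragm level. The array labelled occlusion diaphragm 1 had a median position of 0.18. The other 3 occlusion intercostal arrays lay between -0.038 and 0.086, and the other 3 occlusion diaphragm arrays between 0.91 and 1.12. On 321 features higher in control intercostal, these positions were 0.66 for the array labelled occlusion intercostal 1 and 0.29 for the array labelled occlusion diaphragm 1. Over the whole array as deposited, on 881 features higher in control diaphragm, these 2 arrays lay at 0.80 and 0.38 in that order. The lower quartile of the first was -0.0048 and the upper quartile of the second 1.13. The other occlusion intercostal arrays lay between -0.046 and 0.050 there, and the other occlusion diaphragm arrays between 0.93 and 0.94. On 790 features higher in control intercostal the 2 arrays lay at 0.77 and 0.28. Over all 7696 features that differed between the control muscles, both of these arrays were nearer the other muscle at 26.4%, both nearer the muscle of their label at 28.4% and 1 of each at 45.2%; with replicates 2, 3 and 4 both arrays were nearer the muscle of their label at 77.5%, 65.4% and 85.9%. With the spatial trend removed within brightness classes, over 7204 features, the shares for these arrays were 39.9%, 18.6% and 41.5%. Across all features tested, the array labelled occlusion intercostal 1 had a median correlation of 0.935 with control intercostal and 0.909 with control diaphragm arrays, and the array labelled occlusion diaphragm 1 had 0.937 and 0.926; features are not independent replicates. On the first principal component they lay at -29.1 and 0.391, between the other arrays of the muscles. Every comparison below that uses occlusion arrays includes these 2 arrays as labelled unless stated.

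**Figure D1:**
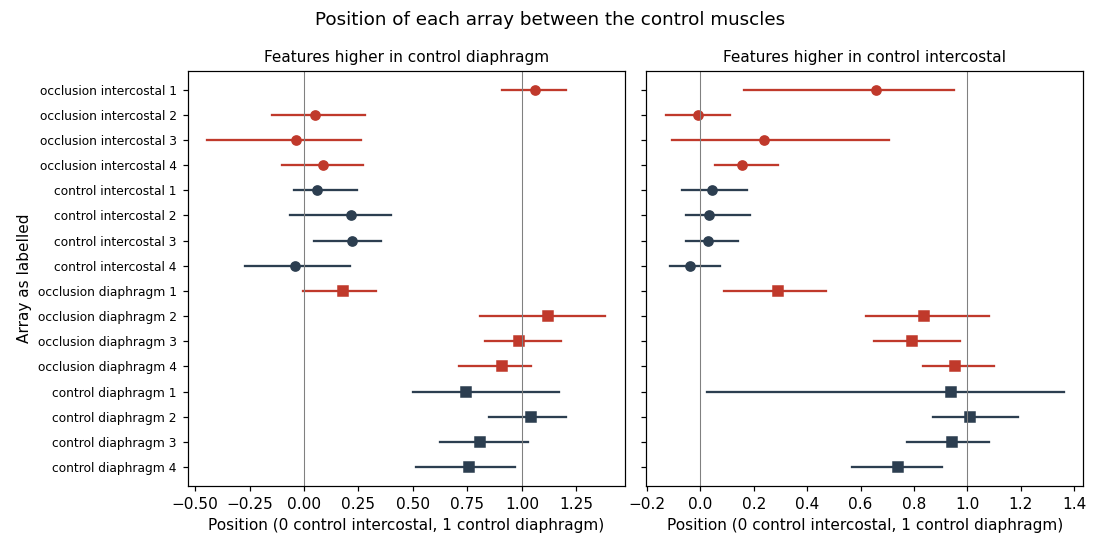
Position of each array between the control muscles (x axis, 0 control intercostal, 1 control diaphragm) for features higher in control diaphragm (left) and in control intercostal (right), in rows from 281 on; points are medians over features (occlusion red, control dark blue, intercostal circles, diaphragm squares) and lines run from the lower to the upper quartile. The array labelled occlusion intercostal 1 lies at 1.06 on the left and the array labelled occlusion diaphragm 1 at 0.18.

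Signal also depended on where a feature lay on the array. Smooth trends over the surface held between 6.65% and 39.5% of the variance of each array's deviations, with a median of 29.7%. In rows 1 to 200 the median log2 deviation in the first columns was above 0 on the intercostal slide and below 0 on the diaphragm slide: it lay between 0.14 and 0.36 on the other 7 intercostal arrays and between -0.38 and -0.18 on the other 7 diaphragm arrays. It was 0.12 on the array labelled occlusion intercostal 1 and -0.11 on the array labelled occlusion diaphragm 1.

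**Figure D2:**
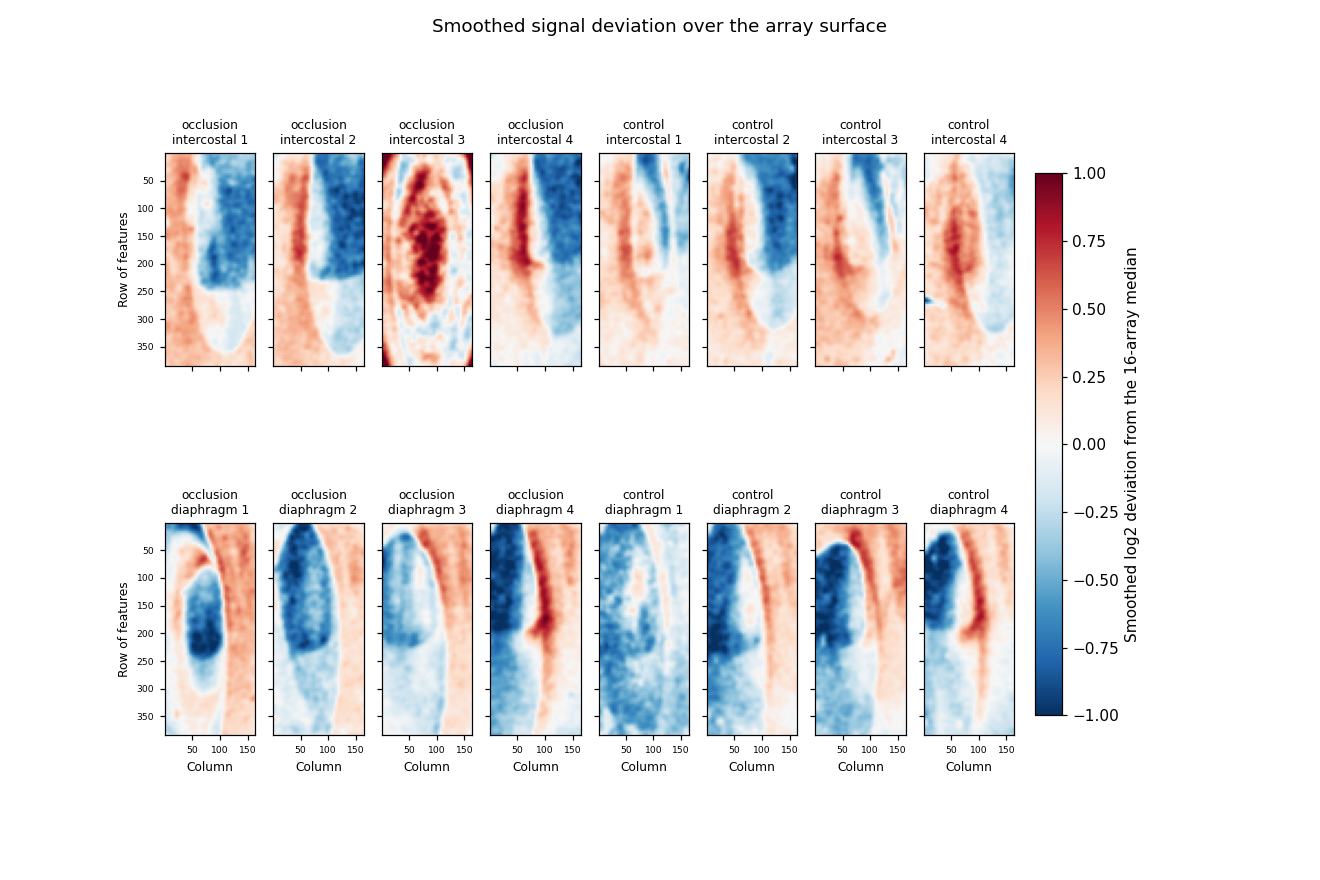
Smoothed log2 deviation of each array from the median over the 16 arrays, drawn over the inferred layout of 384 rows and 164 columns (axes in features). Red is above and blue below the median; the first columns are above it on most intercostal arrays and below it on most diaphragm arrays.

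The first comparison asked which features differed between the muscles of control rats. Diaphragm and intercostal muscle differed at 7696 of 37786 features (limma, adjusted p under 0.05, n = 4 per muscle), of which 3042 were higher and 4654 lower in diaphragm, and 5308 differed more than 2-fold. The spread in this test was estimated from the arrays of all groups. The arrays labelled occlusion intercostal 1 and occlusion diaphragm 1 therefore enter it, and the p-values do not rest on the control SDs alone. Feature 48656 was 123-fold higher in control diaphragm, with a log2 level of 16.68 ± 0.29 against 9.74 ± 0.85 (SD, n = 4 each; limma adjusted p = 0.0056). The standard error of its difference in that fit was 1.55. Feature 11693 had nearly the same levels, 16.69 ± 0.27 against 9.76 ± 0.72 (SD, n = 4 each; limma adjusted p = 0.0045). Lower in diaphragm were feature 39209, at 7.25 ± 0.58 against 13.52 ± 1.59 (SD, n = 4 each; limma adjusted p = 0.0042), and feature 25127, at 7.04 ± 1.13 against 12.57 ± 0.29 (SD, n = 4 each; limma adjusted p = 0.00065).

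The direction of these differences varied with the place of the feature. In the rows before 281, 443 features were higher and 2407 lower in diaphragm in the first columns, and 2278 were higher and 237 lower in the last columns. In the rows from 281 on most were lower on both sides, with 103 higher and 1641 lower in the first columns and 218 higher and 369 lower in the last columns. With the spatial trend removed within brightness classes, 7204 features passed, 3197 higher and 4007 lower, and 4187 features passed in both. With row of the array as a block and the muscles compared at row 1, where each control group has 1 array, 0 features passed (limma, smallest adjusted p = 0.0599); compared at the mean of the rows, which was chosen after that result was seen, 5388 passed. Shifting the arrays to a common median gave 3979 higher and 3728 lower. In occlusion rats, as labelled, 5067 features differed between the muscles, 3150 higher and 1917 lower in diaphragm, so that 62.2% were higher against 39.5% in control rats. The 3070 features that passed in both treatments had the same direction in both. A slide effect would also give this, since both treatments of a muscle lay on the same slide.

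On the 2 arrays out of place, feature 48656 had log2 levels of 16.64 on the array labelled occlusion intercostal 1 and 10.15 on the array labelled occlusion diaphragm 1. The other 3 occlusion diaphragm arrays had between 15.70 and 16.92, and the other occlusion intercostal arrays had 9.01, 8.88 and 12.99. Feature 39209 had 8.39 on the array labelled occlusion intercostal 1 and 13.19 on the array labelled occlusion diaphragm 1. Feature 25127 did not follow this on both arrays: it had 10.67 on the array labelled occlusion intercostal 1, nearer the control intercostal mean, 10.96 on the array labelled occlusion diaphragm 1, and 8.64 on the array labelled occlusion intercostal 3.

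**Figure D3:**
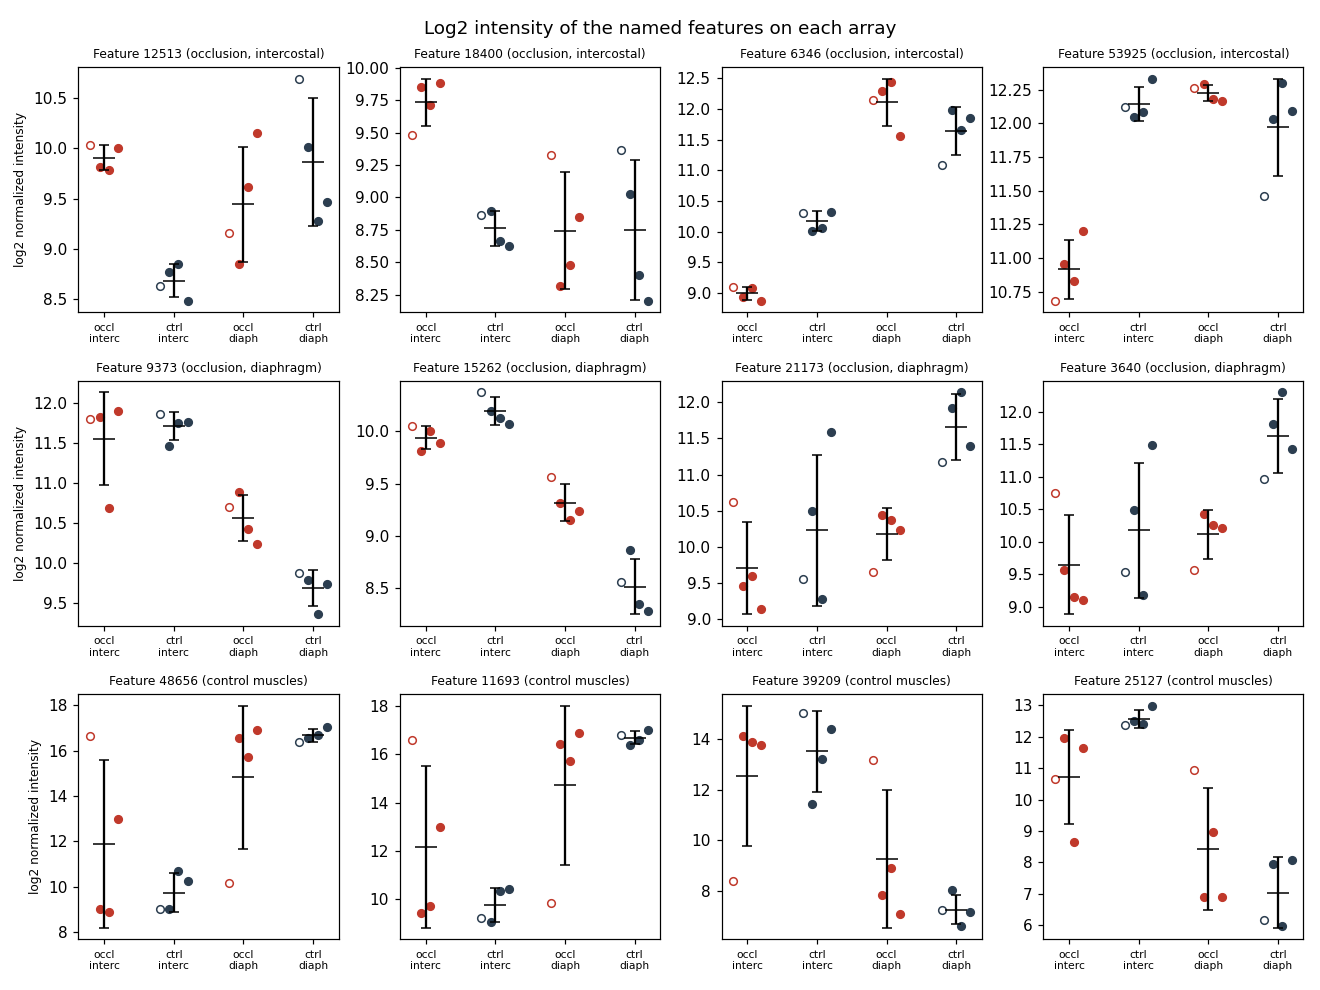
Log2 normalized intensity (y axis) of the 12 named features on each array, by group (x axis; occlusion red, control dark blue), with replicate 1 as open points and bars for means with SD (n = 4). On features 48656 and 39209 the open occlusion points lie with the other muscle.

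The second comparison asked which features occlusion changed in intercostal muscle. No feature passed the threshold (0 of 37786, limma, smallest adjusted p = 0.339, n = 4 per group), and a plain test with equal variances also gave 0. At an unadjusted p under 0.05 there were 4031 features, 1064 higher and 2967 lower with occlusion, against 1889 expected without any effect. With each array left out in turn this number ran from 2331, without the array labelled control intercostal 4, to 8082, without the array labelled occlusion intercostal 3. Groups did not overlap at 3454 features, which is 9.14% of those tested against 2.86% by chance. The 95% interval of the change lay within 2-fold at 59.2% of features and within 4-fold at 93.8%. Among features not past the threshold, feature 12513 had log2 levels of 9.91 ± 0.13 with occlusion and 8.69 ± 0.16 in controls, and feature 18400 had 9.73 ± 0.18 and 8.76 ± 0.14 (SD, n = 4 each; limma adjusted p = 0.339 for both). Feature 6346 had a log2 difference of -1.18 from the control level of 10.18 ± 0.16, and feature 53925 had 10.92 ± 0.22 and 12.14 ± 0.12 (SD, n = 4 each; limma adjusted p = 0.339 for both).

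The count in intercostal muscle stayed at 0 with any 1 array left out, and changed with the model of the spread and with 2 arrays left out together. It was 3438 features (1583 higher, 1855 lower) with array weights and 85 features, all lower, when all 16 arrays shared the estimate of spread. Without the arrays labelled occlusion intercostal 1 and 3, which leaves 2 occlusion arrays, it was 748 features (666 higher, 82 lower) as deposited and 2314 (1811 higher, 503 lower) with the trend removed within brightness classes; leaving out these arrays was decided after the data were seen.

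The third comparison asked the same of the diaphragm. No feature passed the threshold (0 of 37786, limma, smallest adjusted p = 0.999, n = 4 per group), a plain test with equal variances also gave 0, and array weights gave 3. At an unadjusted p under 0.05 there were 800 features, 593 higher and 207 lower, against 1889 expected without any effect. With each array left out in turn this number ran from 387 to 2597, and only without the array labelled occlusion diaphragm 4 did it exceed the expected number. Groups did not overlap at 589 features, 1.56% of those tested against 2.86% by chance. The 95% interval of the change lay within 2-fold at 74.8% of features and within 4-fold at 95.7%. Feature 9373 had log2 levels of 10.56 ± 0.29 with occlusion and 9.69 ± 0.23 in controls, and feature 15262 had 9.32 ± 0.18 and 8.51 ± 0.27 (SD, n = 4 each; limma adjusted p = 0.999 for both). Feature 21173 had 10.18 ± 0.36 with occlusion and 11.66 ± 0.45 in controls, and feature 3640 had 10.12 ± 0.38 and 11.63 ± 0.57 (SD, n = 4 each; limma adjusted p = 0.999 for both). The latter 2 features correlated at 0.990 over the 16 arrays. Other features of largest support that were lower with occlusion in diaphragm had nearly the same levels. Repeated features of 1 probe could not be set aside, so these may not be separate results.

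**Figure D4:**
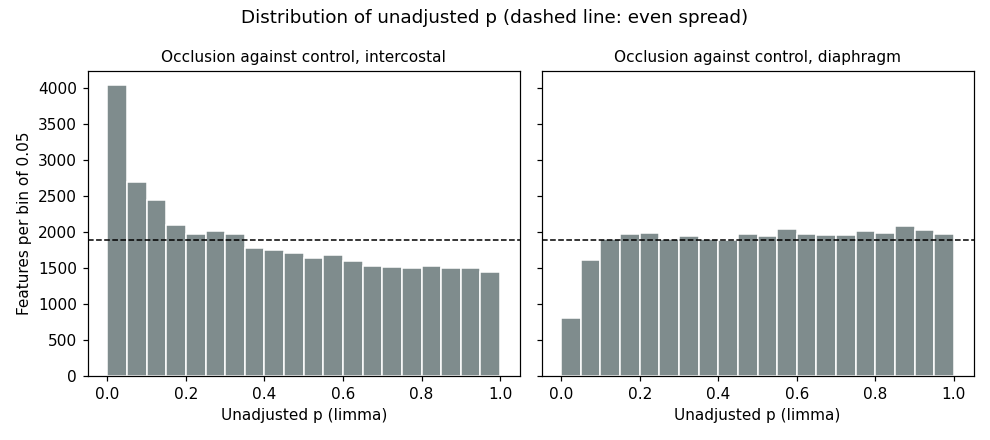
Number of features (y axis) per bin of unadjusted limma p (x axis) for occlusion against control in intercostal muscle (left) and diaphragm (right). The dashed line is the even spread of 1889 per bin; the lowest bin holds 4031 features in intercostal muscle and 800 in diaphragm.

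The difference of the occlusion effects between the muscles was tested directly. No feature passed (0 of 37786, limma interaction contrast, smallest adjusted p = 0.202), with 4103 features at an unadjusted p under 0.05, 3172 with the higher effect in diaphragm and 931 with the lower. With each array left out in turn the number at an unadjusted p under 0.05 ran from 2645, without the array labelled control diaphragm 1, to 6193, without the array labelled occlusion intercostal 3. Array weights gave 6552 features. Across features, the occlusion effects of the muscles correlated at -0.25 (Pearson) and -0.29 (Spearman); features are not independent replicates. Without replicate 1 of every group the correlation was -0.0088.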

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

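The tests of arrays out of place and of the spatial pattern were chosen after the results were seen; the counts of other splits were not, except those by animal code, those with the trend removed and the count of correlations in absolute size. The comparisons with other row blocks and without single arrays as a cause were also chosen after. Dixon's test for a sample far from the others of its group was applied to 80 groups of values and singled out 10, against about 4 by chance (1 in 20).

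The array labelled occlusion intercostal 1 lay far from its group on features higher in control diaphragm, at a position of 1.06 in the rows from 281 on (others -0.038 to 0.086) and at 0.959 over the whole array on features at least 8-fold higher there (others -0.097 to -0.0125). Feature 39209 had a log2 level of 8.39 on that array (others 13.78 to 14.14), and feature 11693 had 9.83 on the array labelled occlusion diaphragm 1 (others 15.75 to 16.89). On features higher in control intercostal in the rows from 281 on, the arrays labelled occlusion intercostal 1 and occlusion diaphragm 1 lay less clearly with the other muscle, at 0.66 and 0.29. Over the whole array with the trend removed within brightness classes they lay at 0.813 and 0.236.

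An exchange of the RNA samples of these 2 arrays before hybridisation needs a partner out of place in the other muscle. On 14 features at least 8-fold higher in control diaphragm it was there, at 0.959 on the array labelled intercostal and -0.039 on the array labelled diaphragm. On 4 features at least 8-fold higher in control intercostal it was less clear, at 0.557 and 0.247. Repeated features of 1 probe could not be set aside, so these sets may hold few separate probes. Over all 7696 features that differed between the control muscles the sides were mixed. Of these, 2029 had both nearer the other muscle, 2185 both nearer the muscle of their label and 3482 had 1 of each. With the trend removed within brightness classes 2877 of 7204 were both nearer the other muscle and 1339 both nearer the muscle of their label. An exchange of the data columns after hybridisation is argued against by the spatial pattern, since the array labelled intercostal carried a deviation of 0.123 in the first columns, on the side of its own slide. The smooth spatial pattern itself is argued against by positions of 0.853 and 0.271 with the trend removed, on features higher in control diaphragm. These lie outside the range of the other 7 arrays of each label. A shift of occluded muscle to the other muscle's profile is argued against by the other 3 occlusion intercostal arrays. Their highest position on features higher in control diaphragm was -0.0125 on the 14 features, 0.0509 with the trend removed and 0.0857 in rows from 281 on. On features higher in control intercostal the array labelled occlusion intercostal 3 reached 0.238 in those rows. A mix of both muscles' RNA in the array labelled diaphragm stays open. Its linear share of the diaphragm level was -0.00917 on the 14 features at least 8-fold higher in control diaphragm. On features at least 2-fold higher there it was 0.283 over 881 features, 0.192 with the trend removed and 0.115 in rows from 281 on. On features higher in control intercostal it was 0.39 over 790 features, 0.337 with the trend removed and 0.394 in rows from 281 on. In the array labelled intercostal the share of 0.899 on the 14 features lies above the lowest of a control diaphragm array, 0.563. On 321 features higher in control intercostal in rows from 281 on, the share of the array labelled intercostal was 0.756. The lowest of a control diaphragm array there was 0.829. Over 790 such features of the whole array the share was 0.84, above the lowest of a control diaphragm array, 0.803. These sets do not decide between a part mix in the array labelled intercostal and diaphragm RNA alone. An exchange of the RNA samples, in full or in part, remains a candidate explanation, found and tested on the same data, and with the trend removed the whole profile of the array labelled diaphragm was nearer control intercostal (r 0.960) than control diaphragm arrays (0.939), while that of the array labelled intercostal did not decide (0.943 and 0.942); both arrays bear the same animal code and the same position on their slides.

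The difference between the control muscles was weighed against the spatial pattern. The share of calls higher in diaphragm differed by 75.1 percentage points between the last and the first columns before row 281, as a pattern that differs between the slides would give, and by -7 points after the trend was removed within brightness classes. The smooth pattern as the whole cause, as far as this removal captures it, is argued against by the 7204 features that passed with the trend removed. Chance is argued against for the count: 1 of 35 splits of the 8 control arrays, the real one, gave as many as 7696 features. The highest other gave 6. A share of 1 in 35 is the smallest that these splits can give. Each other split puts arrays of both muscles in both groups, which widens the spread and lowers its count. These splits alone therefore do not exclude chance. Muscle and slide coincide, so a slide effect that is not smooth over the surface stays open.

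In intercostal muscle more features than expected had an unadjusted p under 0.05. Chance could not be excluded: 2 of 35 splits gave as many as the real 4031, and the highest other, 5476, set the arrays labelled occlusion intercostal 1, 2 and 4 and control intercostal 2 against the rest, which are the arrays with the lowest deviations in the last columns. With the trend removed within brightness classes 2 of 35 splits again gave as many as the real 3882. The highest other, 5897, was the same split as before, and its count had not fallen. The removal may thus have missed structure of the arrays tied to that pattern. The smooth pattern as the whole cause, as far as this removal captures it, is argued against by the 3882 features left. The count was 8082 without the array labelled occlusion intercostal 3, which argues against that array as the cause. With the row of the array on the slide as a block it was 2153, and 2 of the other 15 equally uneven blocks gave fewer. This does not settle whether row has a part in the count. On both slides most occlusion arrays lay in row 1 and most control arrays in row 2. Row and treatment therefore cannot be fully told apart in either muscle.

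For the diaphragm, 26 of 35 splits gave as many features as the real 800 and the highest other gave 5611, so chance could not be excluded. Why that other split gave so many features was not tested. For the difference of the effects between the muscles 1 of 35 splits, the real one, gave as many as 4103 features and the highest other gave 3541. This is the smallest share that 35 splits can give, the margin is narrow and no feature passed the adjusted threshold. These splits alone therefore do not exclude chance. Control positions 3 and 4 come from different animals in the muscles; with arrays joined only where the animal codes match, 1 of 55 splits gave as many and the highest other again gave 3541. The count is not stable to single arrays, since it ran from 2645 to 6193 with each left out, and the arrays out of place enter it on both sides. For the correlation of the effects, 4 of 35 splits gave an r as large in absolute size as the real -0.253, the largest other being -0.341, so chance could not be excluded. With arrays joined by animal code it was 5 of 55, again with -0.341. The count first fixed looked for a higher r only, which a negative r cannot test.

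The arrays labelled occlusion intercostal 3 and control diaphragm 1 are those without a floor and with the highest maximum intensities, 3050000 and 1040000. The array labelled occlusion intercostal 3 had a log2 75th percentile of 10.08 (others 11.63 to 11.79), an interquartile range of 3.36 (others 4.20 to 4.25), a median correlation with its group of 0.874 (others 0.937 to 0.942) and a log2 level of 10.68 for feature 9373 (others 11.80 to 11.89). The array labelled control diaphragm 1 had a median correlation with its group of 0.922 (others 0.970 to 0.971). The array labelled control intercostal 4 had a position of -0.039 on features higher in control intercostal (others 0.030 to 0.043).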

How the results depend on the processing

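The removal of spatial trends, the restriction to rows from 281 on, the comparison at the mean of the rows and the omission of arrays that stood apart were chosen after seeing the data; the other alternatives were fixed before. The count of 0 for occlusion in intercostal muscle became 3438 with array weights, 85 with all 16 arrays in the fit and 86 with animal code as a random block there. Without the arrays labelled occlusion intercostal 1 and 3 it was 748 as deposited, 2314 with the trend removed within brightness classes and 983 with 1 trend removed; the cause was not tested. It stayed at 0 under the other alternatives, including each array left out in turn (0 to 0, with 2331 to 8082 features at an unadjusted p under 0.05; without occlusion intercostal replicate 3 the number was 8082, and without control intercostal replicates 1, 3 and 4 it was 2531, 2623 and 2331). The replicate block gave 0 for both muscles; same-numbered occlusion and control arrays deviated together at between -0.13 and 0.18 in intercostal muscle and between 0.10 and 0.34 in diaphragm. The count of 0 in diaphragm became 3 with array weights and stayed at 0 otherwise, including each array left out (0 to 0), the 2 arrays that stood apart left out, and both ways of removing the trend.

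The count of 0 for the difference of the effects became 6552 with array weights, and ran from 0 to 98 with each array left out: 49 without occlusion intercostal replicate 4 and 98 without control intercostal replicate 2, all with the higher effect in diaphragm. With animal code as a random block it was 0, and the difference between the control muscles was 7351. That difference, 7696 features, became 15334 with no filter, 3228 with the 60% dimmest features left out, 16842 with array weights, 14100 without the 4 arrays that stood apart and 2580 in rows from 281 on, where fewer features were tested; it ran from 5321 to 10100 with each array left out. With row as a block it was 0 (smallest adjusted p 0.0599) in the coding run first, at row 1, where each control group has 1 array, and 5388 at the mean of the rows. The share higher in diaphragm was 39.5%, and 51.6% with a common median, 28.8% with no filter and 15.7% in rows from 281 on. With 1 trend for all features removed it was 10366 features, but 2705 were higher and 1586 lower in the first columns and 513 higher and 3103 lower in the last columns before row 281, a pattern opposite to the one as deposited. The correlation of the effects, -0.253, became -0.0977 without the 4 arrays and ran from -0.334 to -0.00881 with each replicate number left out, the latter without replicate 1. No named feature changed direction under any alternative run. The named features were chosen for groups without overlap on these arrays, so leaving out 1 array could not reverse them. Whether they passed the threshold did change: features 6346 and 53925 passed in 6 alternatives each, 18400 in 4 and 12513 in 3. Features 48656, 11693, 39209 and 25127, which passed in the main test, each failed to pass in 1. Averaging probes per gene and the tests of gene lists could not be run without probe names; all probes were tested singly throughout.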

Other observations

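The tests and counts here were chosen after the results were seen. Of the 12 features of largest support that were lower with occlusion in intercostal muscle, 6 lay within rows 319 to 329 and columns 109 to 133, a box drawn around the largest group of them after they were seen, which holds 0.466% of the features tested. In it 45 of 176 features had an unadjusted p under 0.05 (limma), against 10.7% of all features tested. The 45 include the 6 around which the box was drawn, which raises the count. The median log2 difference in the box was -0.14 as deposited and -0.04 with the trend removed within brightness classes. Feature 53925 is among these 6. Features 48656 and 11693 correlated at 0.997 over the 16 arrays with a median difference of 0.13, and features 21173 and 3640 at 0.990 with a median difference of 0.10, although each pair lies far apart on the array.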
